A study of Mus musculus with 10 samples.

How the data were processed

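Total RNA of brown adipose tissue from 10 libraries of C57BL/6J mice was sequenced: 4 control libraries on regular chow, and 3 obesity-prone and 3 obesity-resistant libraries on a high-fat diet. Per the labels' protocols, clean reads were aligned with Bowtie2 2.2.5 to a gene set built by the sequencing company that holds known and new, coding and noncoding transcripts, and RSEM 1.2.12 computed the expression values. The submitters' processing notes also name HISAT2 2.0.4 and the genome build GRCm38.p6. The deposited table gives, for 32889 genes, the RSEM expected count in each library, which is not normalised. It also gives an FPKM value per gene and library, whose scale followed the authors' count totals to within 0.146%, against a gap of up to 3.43% for the scale of TPM. Of the count values, 30.4% were not whole numbers. The 6 columns that hold the authors' group means were not used. Neither a strand setting nor an annotation release is stated, and no library or sequencing batch is given.

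Gene identifiers were matched to the RefSeq annotation of GRCm38.p6, from which gene class, chromosome, start and end were taken. Of the 25017 genes with a numeric identifier, 24346 matched and 671 did not. A further 7872 genes carried only the sequencing company's own identifier and no name. In 26 symbols a date had replaced the name, and these were restored from the identifier. The annotation made 17618 genes protein-coding and 6349 long noncoding RNAs (lncRNAs). Protein-coding genes held 73.6% of all counts, lncRNAs 2.42% and genes without a name 23.7%.

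Total counts lay between 35583997 and 37327770 per library. Such a depth limits the precision of genes with few counts, and a count of 0 over a group was set at a floor of 3 counts. Ratios with 1 to 3 counts in a group are given with an exact 95% interval for counting error only. Expected counts were rounded to whole numbers and analysed in edgeR 4.0.16 under R 4.3.3, with TMM factors, the filterByExpr filter (minimum count 10) and a robust quasi-likelihood fit of 1 coefficient per group over all 10 libraries, so that the 3 groups shared one estimate of spread with 7 residual degrees of freedom. The filter left 19676 genes, among them 14240 protein-coding genes, 2207 lncRNAs and 2756 genes without a name. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene is said to have changed when its adjusted p was below 0.05. CPM values use TMM-normalised library sizes, and log2 fold changes are given with standard errors from the fit. The 3 comparisons were obesity-prone against control, obesity-resistant against control, and obesity-prone against obesity-resistant. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between samples.

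The groups, tests, gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. Of 39 gene lists with 876 named members, 848 members were found. No mitochondrially encoded gene was found by name, though such genes could be among those without a name. Fewer than 5 genes of the mesothelial and epithelial list passed the filter, which left 37 lists. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's own genes move on balance in one direction, were alternatives. For obesity-prone against control libraries the estimated correlation ranged from 0.00089 (insulin signalling) to 0.98 (erythrocyte genes). It was 0.73 for heat shock, 0.76 for macrophage and 0.83 for respiratory chain genes. Where the estimate lay far above 0.01, the p-value at the preset correlation overstates the evidence. For members of a list, counts adjusted over the list alone are given beside counts over all genes tested. A list's score in a library is the mean over members of log2 CPM (prior count 2) minus the gene's mean over libraries.

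The named genes of a comparison were the 8 highest and 8 lowest fold changes among protein-coding genes that changed, had a mean of at least 1 CPM in either group and did not overlap between the groups, and the 4 highest and 4 lowest lncRNAs on the same terms. To these came the 3 members with the lowest p in each of the 8 lists with the lowest p, the genes Ucp1, Dio2, Ppargc1a, Cidea, Elovl3, Adipoq, Lep, Fasn and Scd1, and the 5 genes with the lowest p where fewer than 5 genes qualified. Genes named outside this rule are said to be so. A gene that the rule names and that counts among the control values that stood out is not reported here.

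Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter and a stricter filter (1 CPM in 3 libraries), fits of only the groups compared, the replicate number as a block, limma with trend on log2 FPKM with added constants of 0.5, 0.1 and 1, a fold minimum of 2, and leaving out each library. Added after seeing the data were fits without obesity-prone replicate 3 and control replicate 4, without the genes that have no name, with the skeletal muscle score as a covariate, and, for lncRNAs, without overlapping gene pairs. Because groups share replicate numbers, the correlation of same-numbered libraries' deviations from their group means was checked before calls were compared. Between control and obesity-resistant libraries it was 0.149, 0.121 and 0.187, so these numbers were taken to pair the libraries. Differently numbered pairs reached 0.254 (control replicate 4, obesity-resistant replicate 1) and 0.242 (control replicate 2, obesity-resistant replicate 3). Of 10 libraries, 3 had a same-numbered library as the best partner. Between control and obesity-prone libraries the same-numbered correlations were -0.086, -0.104 and -0.146, and the block was fitted there too. The support for the pairing is thus weak. That pairing comes from the data and not from a label, and without the trend that followed the skeletal muscle score the correlations were -0.279, 0.026 and -0.162.

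Each lncRNA tested was set beside the nearest protein-coding gene within 100 kb, and Spearman's correlation of their fold changes across pairs was compared with 10000 random reassignments of the partner. For the calls shared by both comparisons with control, 20 sets of 10 libraries with no change were drawn from the mean and spread of each gene. Each gene was drawn on its own, and the deviation of the shared controls entered both comparisons. The steps were tested on simulated data with 200 changed genes, picked among genes with a control mean of at least 1 CPM. Genes were drawn independently and no library stood apart, so the rates below need not hold for rarer genes or for the real libraries. In the comparison of obesity-prone with control libraries, edgeR recovered 67 of 100 genes changed 2-fold and 96 of 100 changed 4-fold, with 4.68% of calls false, and DESeq2 recovered 78 and 99 with 22.7% false. For obesity-resistant against control libraries edgeR recovered 65 and 94 with 2.45% false, and for obesity-prone against obesity-resistant libraries 58 and 91 with 8.02% false. The figures were drawn with matplotlib 3.10.9. Reads of near-identical copies (Hspa1a with Hspa1b, Gstm1 with Gstm2, the globin genes) and of overlapping or antisense genes cannot be told apart with certainty in these counts.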

Results

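Gene expression in brown adipose tissue, the heat-producing fat depot, was measured by RNA sequencing in 10 libraries of C57BL/6J mice: 4 control libraries from mice on regular chow, 3 from obesity-prone and 3 from obesity-resistant mice on a high-fat diet. The libraries held between 35583997 and 37327770 counts. Ucp1, the uncoupling protein that defines brown fat, averaged 8667 ± 1731 CPM (SD, n = 4) in control, 6053 ± 2867 (n = 3) in obesity-prone and 9182 ± 551 (n = 3) in obesity-resistant libraries. The first 3 principal components held 30.6%, 19.4% and 14.3% of the variance. On the component with the largest share, control replicates 1 to 3 lay between -55.6 and -34.9, control replicate 4 at 11.1 and obesity-prone replicate 3 at 74.6. Skeletal muscle list scores varied within each group, from -2.95 to 3.78 in control, -3.03 to 0.075 in obesity-prone and -2.41 to 3.38 in obesity-resistant libraries.

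**Figure D1:**
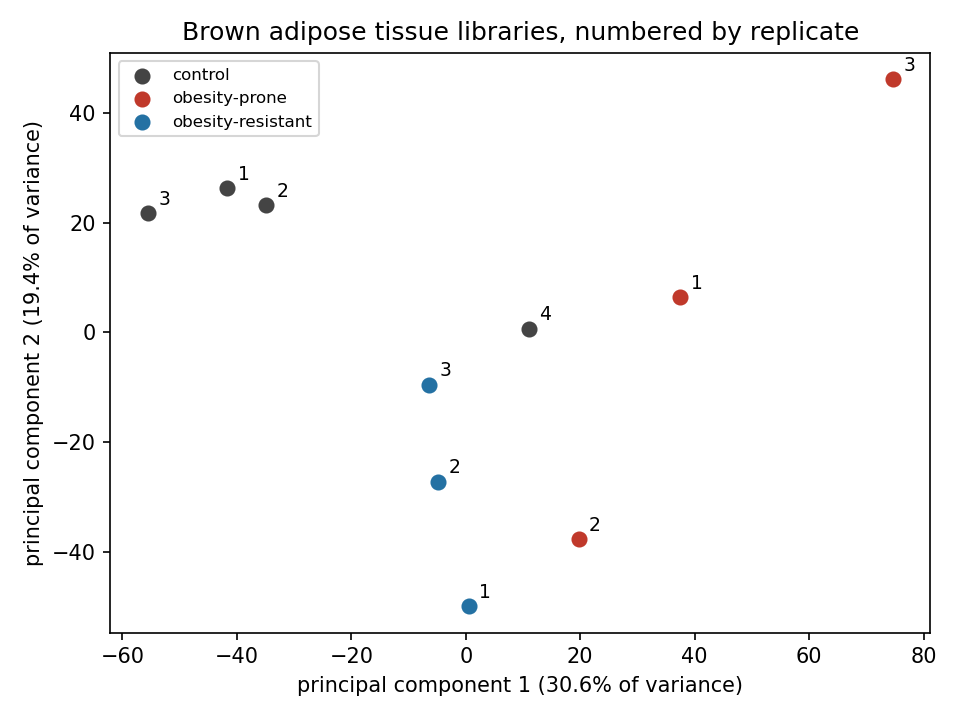
Each point is 1 library (number, replicate) on principal components 1 and 2, with the percent of variance on each axis. Control replicate 4 lies apart from the other controls (11.1 against -55.6 to -34.9 on component 1), and obesity-prone replicate 3 lies farthest out at 74.6.

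The comparison of obesity-prone with control libraries asked how brown fat differs in mice that are prone to obesity on the high-fat diet. At the preset correlation, the lists of heat shock proteins, macrophage genes and extracellular matrix genes were called higher in obesity-prone libraries, and those of branched-chain amino acid breakdown, de novo lipogenesis and the respiratory chain lower. None of the 6 was called with an estimated correlation (adjusted p from 0.45 to 0.47), and of 52 respiratory chain genes 1 passed over all genes tested. Cyp1a1, a cytochrome P450 induced by foreign compounds (identifier 13076, chromosome 9, 57687928 to 57703824), fell from 31.4 ± 8.07 CPM (SD, n = 4) to 1.15 ± 0.798 (n = 3), a log2 fold change of -4.78 ± 0.45 (SE, adjusted p = 0.0025). Cldn1, a tight junction protein (identifier 12737, chromosome 16, 26356645 to 26371839), fell from 16.6 ± 4.70 to 1.60 ± 0.811 CPM (adjusted p = 0.0065). Rspo4, a secreted enhancer of Wnt signalling (identifier 228770, chromosome 2, 151842647 to 151874668), rose from 0.0422 ± 0.0536 to 1.57 ± 0.395 CPM (adjusted p = 0.0091). In all, 730 genes rose and 647 fell, 1377 of 19676 tested by edgeR. Limma on FPKM called 708 higher and 415 lower.

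Among the other protein-coding genes with the largest changes, Hspa1b and Hspa1a (inducible heat shock protein 70), Kcnj14, Scd3 (a stearoyl-CoA desaturase), Crtac1 and Ubd rose, with log2 fold changes from 3.88 to 4.72. Without obesity-prone replicate 3 those of Crtac1, Kcnj14 and Ubd were 1.26 (adjusted p = 0.21), 2.16 (0.036) and 2.25 (0.071), and without obesity-prone replicate 2 that of Hspa1b was 3.09 (0.043) and that of Hspa1a 3.01 (0.053). Slc5a7, the choline transporter, had 1 count over the 4 control libraries and 539 over the 3 obesity-prone ones, a ratio of 678 (95% interval 121 to 26810), and obesity-prone replicate 3 alone reached 12.98 CPM (log2 fold change 8.83, and 5.88 without that library, adjusted p = 0.048). Slc2a5, the fructose transporter, was listed at 0 in the obesity-prone libraries against 388 counts in control, at least 103-fold lower at a floor of 3 counts over the group. Cyp2e1, Magel2, Pim2, Prss8 and Lrrn4 also fell, with log2 fold changes from -3.70 to -2.98, and without obesity-prone replicate 1 that of Pim2 was -5.93. Lep, the adipocyte hormone leptin, rose from 12.2 ± 7.07 to 160.0 ± 204 CPM (log2 fold change 3.71, adjusted p = 0.049), with 394.9 CPM in obesity-prone replicate 3, and without that library the log2 fold change was 1.80 (adjusted p = 0.23). For Ucp1 the log2 fold change was -0.52 (adjusted p = 0.32), and Dio2, Ppargc1a, Cidea, Elovl3, Adipoq, Scd1 and Fasn did not pass either (adjusted p from 0.077 to 0.78). Of the 47 genes that changed among those named for this comparison, 39 lost the call without control replicate 3, and Cyp1a1, Cldn1, Rspo4, Magel2, Lrrn4, Bcat2, Oas2 and the lncRNA Lncenc1 were called whichever library was left out.

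Heat shock proteins, the chaperones of misfolded protein, had a median log2 fold change of 1.52 in obesity-prone libraries. Of 16 members, 12 rose and none fell over all genes tested, and 14 rose when adjusted over the list alone (list adjusted p = 4.7e-14, but adjusted p = 0.45 with an estimated correlation). Hspb1 rose from 45.1 ± 12.3 to 245 ± 192 CPM, Dnajb1 from 30.9 ± 8.53 to 119.5 ± 68.7, and Hspb8 from 42.6 ± 15.0 to 127 ± 36.3. For Hspb1 the log2 fold change was 2.44, and 1.59 without obesity-prone replicate 2. Genes of the unfolded protein and integrated stress responses had a median of 0.43 (adjusted p = 7.5e-07), with 6 of 24 higher and 13 adjusted over the list alone. Immediate early genes had a median of 0.64 (adjusted p = 4.8e-06), with 7 of 25 higher and 1 lower, and 10 higher and 2 lower adjusted over the list alone. Lysosome and autophagy genes had a median of 0.33 (adjusted p = 0.00012), with 4 of 23 higher, and 9 higher and 1 lower adjusted over the list alone. For these 3 lists the adjusted p was 0.45 with an estimated correlation, and fry gave 0.025 for the lysosomal one, whose median was 0.21 without obesity-prone replicate 2.

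Macrophage genes had a median log2 fold change of 1.26, with all 25 members above 0 (adjusted p = 1.6e-10, adjusted p = 0.45 with an estimated correlation). Over all genes tested 4 of them rose, and 21 rose when adjusted over the list alone. Lyz2, which encodes lysozyme, rose from 37.7 ± 8.67 to 92.0 ± 44.4 CPM, Gpnmb from 8.06 ± 3.30 to 34.4 ± 26.7 and Tyrobp from 3.82 ± 1.19 to 10.4 ± 5.41. The log2 fold change of Gpnmb was 1.26 (adjusted p = 0.11) without obesity-prone replicate 3 in place of 2.09. The macrophage score was 1.12 and 1.65 in obesity-prone replicates 1 and 3 and -0.003 in replicate 2. Collagen and extracellular matrix genes had a median of 0.82 (adjusted p = 6.8e-09, adjusted p = 0.45 with an estimated correlation), with 5 of 26 higher, and 18 higher and 1 lower adjusted over the list alone. Serpinh1, the collagen chaperone, rose from 198 ± 49.6 to 495 ± 125.3 CPM, Lox, the collagen-crosslinking lysyl oxidase, from 24.4 ± 3.95 to 72.5 ± 39.3 and Bgn from 65.7 ± 12.3 to 147 ± 51.1. For Lox the log2 fold change was 1.57, and without obesity-prone replicate 3 it was 1.04 and the median of the list 0.52. Inflammatory cytokines and chemokines had a median of 0.99 (adjusted p = 1.1e-07), with 4 of 26 higher and 7 adjusted over the list alone, among them Cxcl1, Tnf and Icam1. Interferon response genes had a median of 0.74 (adjusted p = 3e-08), with 6 of 29 higher, and 12 higher and 1 lower adjusted over the list alone, among them Oas2, Ifit2 and Xaf1. With an estimated correlation the adjusted p was 0.47 for both.

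Other cell type lists passed the test too. Endothelial genes had a median of 0.42 (adjusted p = 2.1e-05, 1 of 19 higher, 6 adjusted over the list alone) and neutrophil and mast cell genes 0.58 (adjusted p = 0.0013, 3 of 10 higher, 4 adjusted over the list alone). Cell cycle genes had a median of 1.07 (adjusted p = 3.4e-05), with none of 22 called either way. With an estimated correlation the adjusted p of these 3 lists was 0.47, 0.45 and 0.47. The median of neutrophil and mast cell genes was 0.28 without obesity-prone replicate 3 and 0.88 without obesity-prone replicate 2 or control replicate 4. White adipocyte-selective genes had a median of 0.83 (adjusted p = 0.011, adjusted p = 0.47 with an estimated correlation), with 5 of 16 higher and 7 adjusted over the list alone. Erythrocyte genes had a median of 2.03 (adjusted p = 0.0013, adjusted p = 0.47 with an estimated correlation), with 0 of 9 called by edgeR either way. Without obesity-prone replicate 3 the medians of the last-named lists were 0.39 (adjusted p = 0.23) and 0.57 (0.17), and that of erythrocyte genes was 3.22 without control replicate 4. The scores of obesity-prone replicate 3 were 1.72 for white adipocyte-selective and 3.20 for erythrocyte genes. Skeletal muscle genes had a median of -3.15 (adjusted p = 0.011, adjusted p = 0.68 with an estimated correlation), and the call ended without control replicate 2 (median -2.01, adjusted p = 0.29), control replicate 3 (0.078) or obesity-prone replicate 2 (0.16).

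Branched-chain amino acid breakdown, by which brown fat burns these amino acids, had a median log2 fold change of -0.50 with all 19 members below 0 (adjusted p = 4.6e-09, adjusted p = 0.45 with an estimated correlation). Of these, 5 fell over all genes tested and 12 when adjusted over the list alone. Bcat2, the mitochondrial branched-chain aminotransferase (identifier 12036, chromosome 7, 45568967 to 45589710), fell from 105 ± 19.04 to 41.7 ± 8.73 CPM (adjusted p = 0.0092), Ppm1k from 51.9 ± 13.7 to 19.9 ± 5.06 and Mccc2 from 83.6 ± 12.8 to 49.5 ± 4.56. De novo lipogenesis genes had a median of -0.49 (adjusted p = 7.5e-07, adjusted p = 0.45 with an estimated correlation), with 5 of 27 lower and 11 adjusted over the list alone, and -0.32 without control replicate 1. Acly, ATP citrate lyase, fell from 680.0 ± 427 to 149 ± 15.9 CPM, Thrsp from 644 ± 347 to 132 ± 56.7 and Tkt from 1176 ± 430 to 440.1 ± 136. The controls were uneven, with Acly at 932, 382, 1147 and 259 CPM in control replicates 1 to 4. Scd1 went apart from the list, with 9929 ± 5944 CPM in control and 11823 ± 2773 in obesity-prone libraries (adjusted p = 0.78). Glucose uptake and glycolysis genes had a median of -0.45 (adjusted p = 6.7e-05, adjusted p = 0.47 with an estimated correlation), with 1 of 27 higher and 3 lower, and 2 higher and 8 lower adjusted over the list alone. That median was -0.26 without obesity-prone replicate 3 (adjusted p = 0.024). In control libraries the score of this list followed that of skeletal muscle genes. In control replicates 1 to 4 it was 0.03, 0.25, 0.40 and -0.08, where the muscle score was -2.84, 3.78, 2.70 and -2.95. In obesity-prone replicates 1 to 3 it was -0.10, -0.05 and -0.68, where the muscle score was -0.22, -3.03 and 0.075. Muscle in the samples may thus enter the median. Cholesterol synthesis genes had a median of 0.42 (adjusted p = 0.0027, adjusted p = 0.47 with an estimated correlation), with 3 of 23 higher and 1 lower, and 10 higher and 3 lower adjusted over the list alone. That call ended without control replicate 4 (adjusted p = 0.064). General adipocyte genes had a median of -0.26 (adjusted p = 0.00039, adjusted p = 0.45 with an estimated correlation, fry 0.034), with 1 of 20 higher and 3 lower, and 1 higher and 7 lower adjusted over the list alone.

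Nuclear-encoded respiratory chain genes had a median of -0.43 (adjusted p = 1.1e-09, adjusted p = 0.47 with an estimated correlation). Of 52 members 1, Ndufc2, fell over all genes tested, from 116 ± 17.5 to 71.2 ± 18.7 CPM, and none when adjusted over the list alone. TCA cycle genes had a median of -0.41 (adjusted p = 0.00017), fatty acid oxidation genes -0.27 (adjusted p = 0.0012) and cytosolic ribosomal protein genes -0.14 (adjusted p = 0.0012), with 0 of 22, 2 of 28 and 1 of 37 lower, and the same counts adjusted over the list alone. With an estimated correlation their adjusted p was 0.56, 0.60 and 0.60. The 3 calls ended without obesity-prone replicate 3, with medians of -0.14 (adjusted p = 0.26), -0.09 (0.66) and -0.08 (0.096), and the respiratory chain was still called at -0.19 (0.00079). Without obesity-prone replicate 2 the median of fatty acid oxidation genes was -0.41. The respiratory chain score was -0.914 in obesity-prone replicate 3 and 0.0194 and -0.0005 in replicates 1 and 2. Lists that did not pass were thermogenesis and brown adipocyte identity (median -0.23, adjusted p = 0.066), sympathetic and adrenergic signalling (-0.29, 0.051), antioxidant and NRF2 targets (-0.29, 0.077), insulin signalling (-0.14, 0.29), nerve and Schwann cell (-0.39, 0.27), MHC class II and dendritic cell (0.28, 0.20), progenitor and fibroblast (0.26, 0.41) and circadian clock (-0.12, 0.69). PPAR alpha-type targets (median 0.14, adjusted p = 0.88), vascular smooth muscle and pericyte (0.07, 0.96) and B cell and plasma cell genes (0.21, 0.57) were tested downward against a median above 0. Creatine and calcium cycling (median -0.21, mean -0.76, adjusted p = 0.64) was tested upward, T and NK cell genes (median -0.18, mean 0.02, adjusted p = 0.95) downward, and the named lncRNAs (median 0.10, mean -0.001, adjusted p = 0.88) upward.

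Of 2207 lncRNAs tested, 58 rose and 60 fell in obesity-prone libraries, and 67 passed when adjusted over the lncRNAs alone. Lncenc1 (identifier 100039691, chromosome 13, 97434970 to 97497664) rose from 0.0561 ± 0.0396 to 1.03 ± 0.185 CPM (SD, n = 4 and 3, adjusted p = 0.0029). 1700047G03Rik, Gm45954 and Gm31522 rose with log2 fold changes of 4.42, 4.22 and 4.13. Without obesity-prone replicate 3 that of 1700047G03Rik was 3.29 (adjusted p = 0.037) and that of Gm31522 3.08 (0.086), and without obesity-prone replicate 2 that of Gm45954 was 2.95 (0.021). Gm39447, Gm32762, Gm35196 and Gm41313 fell, with log2 fold changes of -4.36, -3.34, -3.06 and -2.10. The lncRNA count was 16, 19, 6 and 225 without control replicates 1 to 4, 48 and 30 without obesity-prone replicates 1 and 3, and 66, 54 and 61 without obesity-resistant replicates 1 to 3.

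Leaving out a library moved the count of 1377 genes to 256, 241, 76 and 3034 for control replicates 1 to 4, to 545, 2198 and 539 for obesity-prone replicates 1 to 3 and to 801, 671 and 713 for obesity-resistant replicates 1 to 3, and 76 of the genes were called in every one of these fits. DESeq2 called 3138 genes, a fit of only the 2 groups 49, a fit with the skeletal muscle score 543 and a fit without obesity-prone replicate 3 and control replicate 4 2660.

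**Figure D2:**
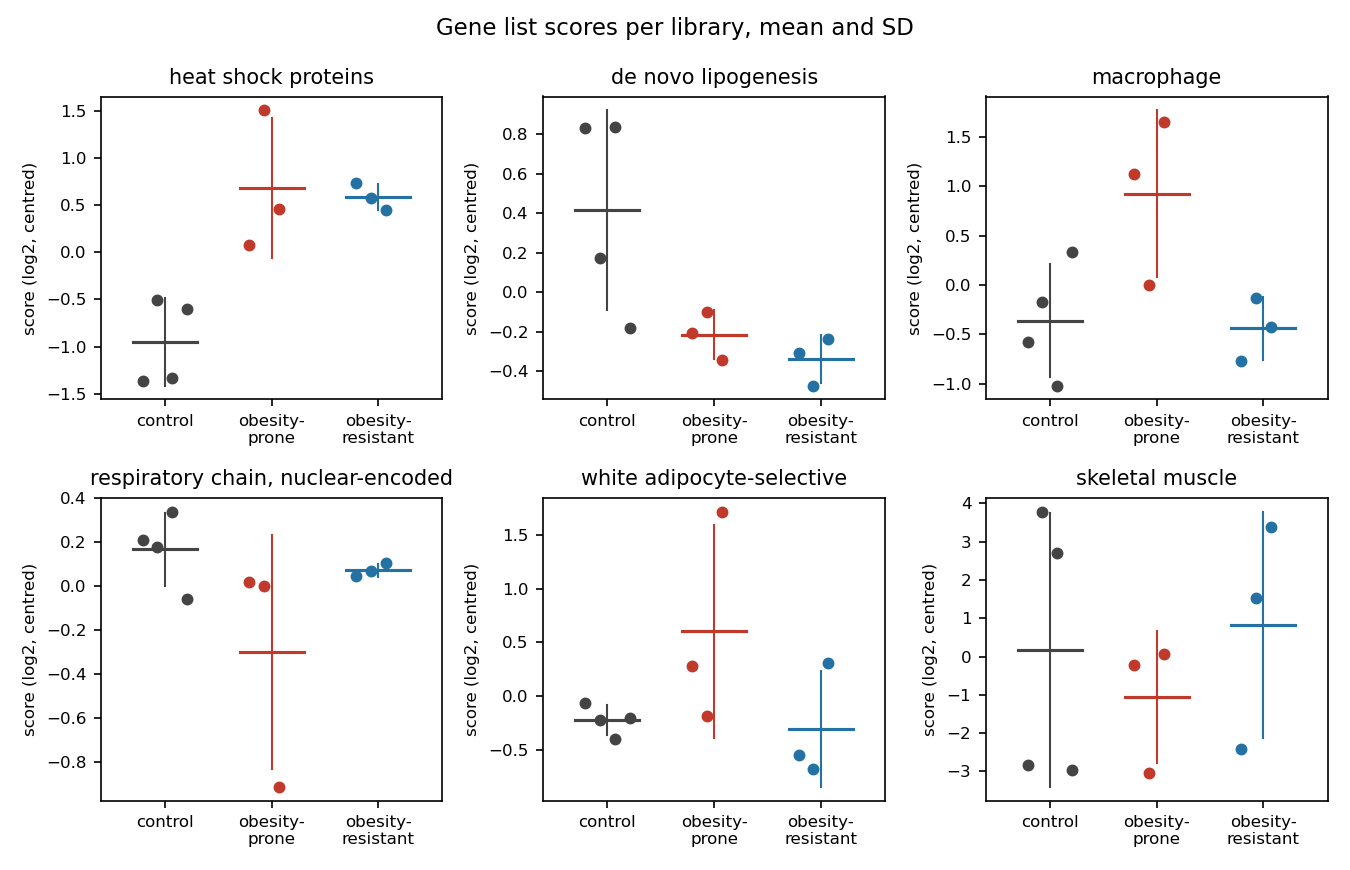
Gene list scores (log2, centred on the mean over libraries) for each library, with the group mean and SD, in 4 control, 3 obesity-prone and 3 obesity-resistant libraries. Heat shock scores lie above every control (highest -0.503) in all 6 high-fat diet libraries, and the lowest respiratory chain score (-0.914) and the highest white adipocyte-selective score (1.72) belong to obesity-prone replicate 3.

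The comparison of obesity-resistant with control libraries asked what the same diet goes with in mice that resist obesity. Ryr2, the calcium release channel of the endoplasmic reticulum (identifier 20191, chromosome 13, 11553099 to 12106945), rose from 27.2 ± 4.88 CPM (SD, n = 4) to 86.0 ± 3.67 (n = 3), a log2 fold change of 1.66 ± 0.15 (SE, adjusted p = 0.0032). Gpc1, a heparan sulfate proteoglycan (identifier 14733, chromosome 1, 92831645 to 92860211), rose from 12.2 ± 1.69 to 41.2 ± 10.2 CPM (log2 fold change 1.75 ± 0.16, adjusted p = 0.0032). Fgf14, a member of the fibroblast growth factor family (identifier 14169, chromosome 14, 123974441 to 124677686), fell from 179 ± 35.3 to 73.0 ± 1.99 CPM (log2 fold change -1.29 ± 0.15, adjusted p = 0.018). The heat shock list was called higher and the lipogenesis list lower at the preset correlation, but neither with an estimated one (adjusted p = 0.33 and 0.55), and none of their members passed over all genes tested. In all, 19 genes rose and 9 fell, 28 of 19676 tested by edgeR. Limma on FPKM called 35 higher and 7 lower.

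The largest increases were those of Bmp8b, a bone morphogenetic protein, from 0.287 ± 0.126 to 2.84 ± 0.622 CPM, and Bdh1, the ketone body dehydrogenase, from 0.140 ± 0.0641 to 1.34 ± 0.582 CPM. Cacna2d3, Wipf3, Acot12 and Cdh9 rose with log2 fold changes from 1.85 to 2.32. Cyp1a1 fell to 3.23 ± 0.985 CPM (log2 fold change -3.28, adjusted p = 0.021), and Magel2, an imprinted gene, fell from 1.79 ± 0.426 to 0.208 ± 0.120 CPM. Zfp185, Col6a6, Angpt1, Pde1a and Gstm2 fell with log2 fold changes from -1.93 to -1.05. The single lncRNA past the test was 9430085M18Rik (identifier 77361, chromosome 5, 101703549 to 101763231), from 0.413 ± 0.0350 to 1.52 ± 0.487 CPM (adjusted p = 0.034). When adjusted over the 2207 lncRNAs alone, 0 passed in edgeR, with 345 at an unadjusted p below 0.05, and DESeq2 called 98. Ucp1, Dio2, Ppargc1a, Cidea, Elovl3, Adipoq, Lep, Fasn and Scd1 did not pass, with adjusted p from 0.094 to 0.92. Of the 17 genes that changed among those named for this comparison, 15 lost the call without control replicate 2 or without obesity-resistant replicate 1 (adjusted p of up to 0.23 without the latter), and Ryr2 and Gpc1 were called whichever library was left out.

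Heat shock proteins had a median log2 fold change of 1.42 with all 16 members above 0 (adjusted p = 4e-21, adjusted p = 0.33 with an estimated correlation). None of them passed over all genes tested and 13 were higher when adjusted over the list alone. Hspb8 averaged 42.6 ± 15.0 CPM in control and 112 ± 8.91 in obesity-resistant libraries (adjusted p = 0.055), and Hspb1 45.1 ± 12.3 and 199.8 ± 40.2 (adjusted p = 0.076). De novo lipogenesis genes had a median of -0.64 (adjusted p = 5e-11, adjusted p = 0.55 with an estimated correlation). None of 27 passed over all genes tested and 14 were lower when adjusted over the list alone. Fasn, fatty acid synthase, averaged 5586 ± 4351 CPM in control and 827 ± 265 in obesity-resistant libraries (adjusted p = 0.094), and Acly 680.0 ± 427 and 153 ± 13.7 (adjusted p = 0.077). The lipogenesis score of control replicate 4, at -0.182, lay among the high-fat diet libraries (-0.472 to -0.0975). In control replicates 1 to 3 the score was 0.833, 0.176 and 0.838. Fasn was at 8816, 2401, 9819 and 1309 CPM in control replicates 1 to 4, so its high control mean rests on replicates 1 and 3.

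Antioxidant and NRF2 targets had a median of -0.20 (adjusted p = 0.0029, adjusted p = 0.33 with an estimated correlation, fry 0.040), with Gstm2 lower over all genes tested, and 5 of 22 lower and 1 higher adjusted over the list alone. General adipocyte genes had a median of -0.21 (adjusted p = 0.0035, 1 higher and 4 lower adjusted over the list alone), branched-chain amino acid breakdown -0.19 (adjusted p = 0.0060, 4 lower) and cytosolic ribosomal proteins -0.11 (adjusted p = 0.0018, 0 either way), with none called over all genes tested. Their adjusted p was 0.55, 0.92 and 0.92 with an estimated correlation. The branched-chain median was -0.12 without control replicate 3 or obesity-resistant replicate 2, and the ribosomal one -0.18 and -0.07 without obesity-resistant replicates 2 and 3. Unfolded protein and integrated stress response genes had a median of 0.17 (adjusted p = 0.00080, adjusted p = 0.73 with an estimated correlation) and 5 members higher adjusted over the list alone, and a median of 0.35 without control replicate 4. Interferon response genes had a median of 0.39 (adjusted p = 0.0029, and 0.13 without obesity-resistant replicate 2), endothelial genes 0.17 (adjusted p = 0.0060, and 0.088 without control replicate 1 or 0.092 without obesity-resistant replicate 1), and lysosomal genes 0.14 (adjusted p = 0.043). The lysosomal call ended without control replicate 1 (0.078) or 3 (0.084) and without obesity-resistant replicate 2 (0.17) or 3 (0.12). Without control replicate 4 the interferon and endothelial medians were 0.64 and 0.36. Without obesity-resistant replicate 2 the interferon and lysosomal ones were 0.25 and 0.09, and the endothelial one was 0.06 without control replicate 1 and 0.09 without control replicate 3 or obesity-resistant replicate 1. With an estimated correlation the adjusted p of these lists was 0.92, 0.92 and 0.73. Lists called lower whose call ended without control replicate 4 were B cell and plasma cell genes (median -1.16, adjusted p = 0.0075, 0.14 without that library), MHC class II and dendritic cell genes (-0.32, 0.0060, 0.072 without it) and progenitor and fibroblast genes (-0.30, 0.011, 0.14 without it and 0.061 without obesity-resistant replicate 1). With an estimated correlation their adjusted p was 0.73, 0.66 and 0.92. The B cell and plasma cell median was -0.77 without control replicate 4, the MHC class II one -0.49 without obesity-resistant replicate 2 and the progenitor one -0.59 without obesity-resistant replicate 3. Creatine and calcium cycling was called upward (adjusted p = 0.043, adjusted p = 0.66 with an estimated correlation) with a median of 0.01 and Ryr2 as its changed member, and the call ended without control replicate 1 (0.088) or obesity-resistant replicates 2 (0.12) and 3 (0.12). Its median was 0.15 without control replicate 2 and 0.17 without obesity-resistant replicate 1. The score of this list followed that of skeletal muscle genes. In control replicates 1 to 4 it was -1.14, 1.10, 0.68 and -0.76, where the muscle score was -2.84, 3.78, 2.70 and -2.95. In obesity-resistant replicates 1 to 3 it was -0.80, 0.58 and 1.10, where the muscle score was -2.41, 1.52 and 3.38. Macrophage genes, with a median of -0.23 (adjusted p = 0.20), and the respiratory chain, with -0.14 (adjusted p = 0.087), did not pass, nor did the other lists (adjusted p from 0.058 to 0.99).

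With the replicate number as a block, which pairs control and obesity-resistant libraries and leaves out control replicate 4, 383 genes and 33 lncRNAs changed, among them all 28 genes called without it, against 856 and 76 in the same libraries without the block. The count of 28 was 7, 3, 8 and 856 without control replicates 1 to 4, 193 and 300 without obesity-prone replicates 2 and 3 and 3, 6 and 4 without obesity-resistant replicates 1 to 3, and that of lncRNAs was 76 without control replicate 4, 2, 18 and 22 without obesity-prone replicates 1 to 3 and 0 without control replicate 1, 2 or 3 or obesity-resistant replicate 1 or 2. DESeq2 called 1138 genes, a fit of only the 2 groups 361, and a fit without obesity-prone replicate 3 and control replicate 4 2214. Fits of only the 2 groups thus gave 49 genes for obesity-prone and 361 for obesity-resistant against control libraries. The order of the 2 counts depends on the spread shared by the 3 groups, and the counts do not rank the groups by distance from control. Between 2 libraries, the chi-square of the counts per degree of freedom was 37.7 to 158 within obesity-prone and 25.7 to 33.1 within obesity-resistant libraries.

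**Figure D3:**
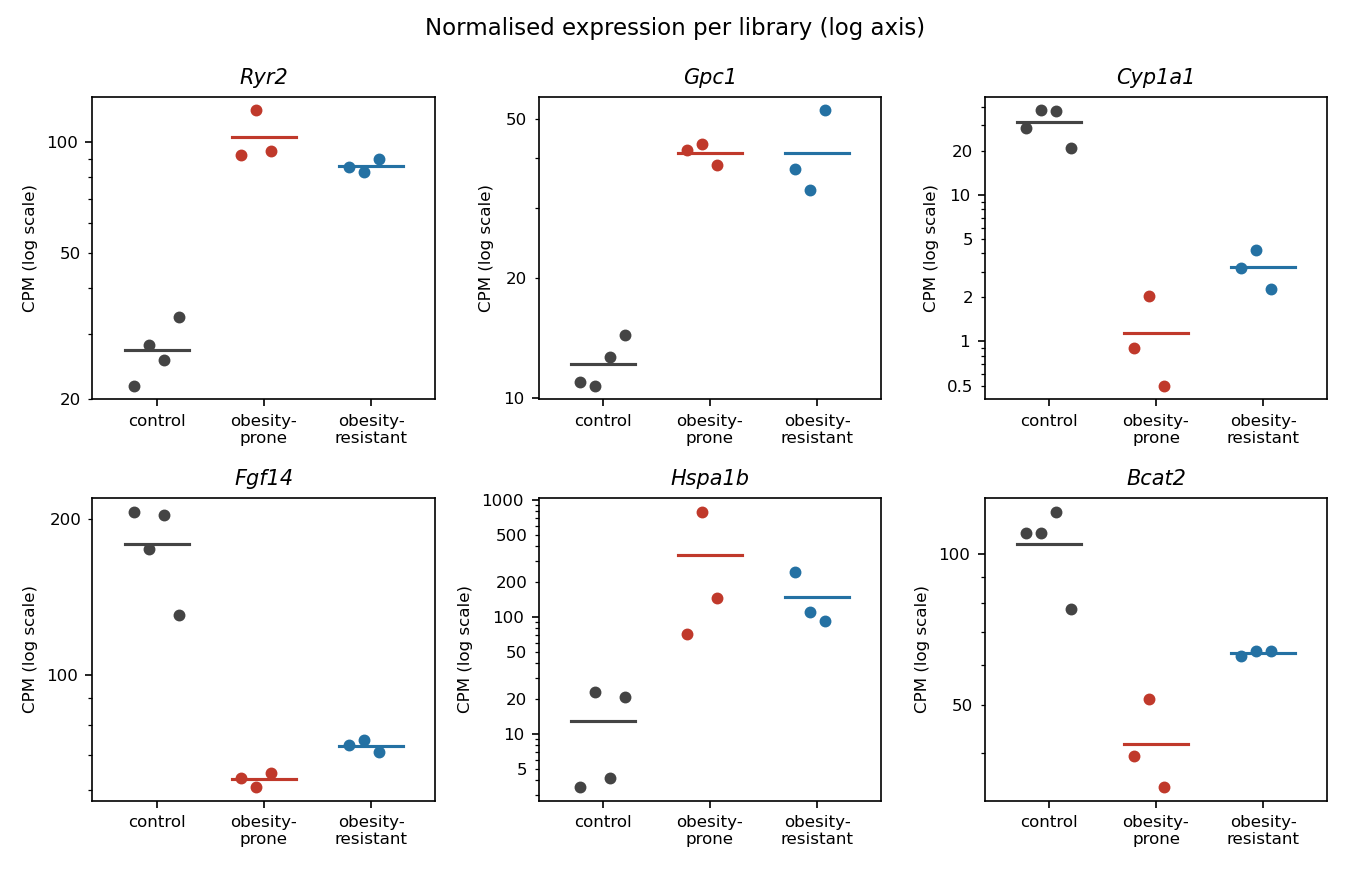
CPM of 6 genes in each library on a log axis, with a line at the group mean, in 4 control, 3 obesity-prone and 3 obesity-resistant libraries. Ryr2 and Gpc1 lie higher and Cyp1a1, Fgf14 and Bcat2 lower in each high-fat diet library than in each control, and Hspa1b ranges from 71.8 to 792.9 CPM in obesity-prone libraries.

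The 2 comparisons with control shared 25 of their calls, 17 upward and 8 downward, and no gene was called in opposite directions. Shared increases were Ryr2 (log2 fold change 1.92 in obesity-prone and 1.66 in obesity-resistant libraries), Gpc1 (1.76 and 1.75) and the laminin subunit Lamb3 (1.81 and 1.59), which was named after its values were seen and had the lowest adjusted p in both (5.5e-05 and 0.00020). These 3 were called in each of the alternative fits of both comparisons. Shared decreases were Cyp1a1, Magel2, Zfp185, Col6a6, Fgf14, Angpt1, Pde1a and Ndn, the last of which was also named after its values were seen. Bdh1, Acot12 and Gstm2 were called in obesity-resistant but not in obesity-prone libraries against control (adjusted p of 0.31, 0.060 and 0.063 in the latter). Independent lists of these lengths share 0.705 genes upward and 0.296 downward on average. In 20 simulated draws with no change no gene was called in either comparison, so the draws give no chance value for the shared calls. Fold changes correlated across genes, which are not independent replicates, at Pearson's r = 0.54, with a covariance of 0.173. The shared controls alone gave 0.43 (0.38 to 0.47) and a mean covariance of 0.061 in those draws. The draws treat genes as independent, whereas genes of the real libraries vary together. Their range is thus too narrow to tell whether 0.54 exceeds what the shared controls give. With the controls split 2 and 2 between the comparisons, 1 to 17 calls were shared, r was 0.019 to 0.40 and the covariance 0.0098 to 0.153. The count of 25 was 6, 3, 8 and 691 without control replicates 1 to 4, 109 and 173 without obesity-prone replicates 2 and 3 and 3, 5 and 4 without obesity-resistant replicates 1 to 3.

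The comparison of obesity-prone with obesity-resistant libraries asked what separates the groups on the same diet. As lists, macrophage, extracellular matrix, cell cycle and erythrocyte genes were higher and respiratory chain, branched-chain amino acid and thermogenesis genes lower in obesity-prone libraries, but none of these held with an estimated correlation. No single gene passed. The lowest adjusted p was 0.23, shared by many genes, of which the 5 with the lowest p were H2-Ab1, an MHC class II chain (35.7 ± 9.47 against 16.9 ± 1.06 CPM, SD, n = 3 each), Comp, a matrix protein (0.544 ± 0.132 against 0.109 ± 0.0261), the phosphodiesterase Pde7b (107 ± 33.0 against 294 ± 62.5), and the lncRNAs Gm34218 (8.79 ± 0.872 against 19.1 ± 1.06) and Gm46489 (1.87 ± 0.387 against 4.15 ± 0.485). EdgeR called 0 of 19676 genes and 0 lncRNAs with 3030 genes at an unadjusted p below 0.05, limma called 0 and DESeq2 565, among them 45 lncRNAs. Leaving out obesity-prone replicate 2 gave 885 genes, 63 of them lncRNAs, and leaving out control replicate 3 gave 1, a lncRNA.

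Macrophage genes had a median log2 fold change of 1.41 with all 25 members above 0 (adjusted p = 4.5e-22, adjusted p = 0.50 with an estimated correlation), and 23 were higher when adjusted over the list alone. Csf1r, the receptor that macrophages need to survive, averaged 39.4 ± 15.5 CPM in obesity-prone and 15.0 ± 1.08 in obesity-resistant libraries, and Lyz2 92.0 ± 44.4 and 30.3 ± 2.57 (adjusted p = 0.23 for both). Collagen and matrix genes had a median of 0.95 (adjusted p = 9.2e-15), with 13 of 26 higher adjusted over the list alone, and Col1a1 averaged 376 ± 202 and 128 ± 29.2 CPM. Cell cycle genes had a median of 0.98 (adjusted p = 7.6e-08, 0 of 22 adjusted over the list alone), MHC class II and dendritic cell genes 0.77 (adjusted p = 4.1e-06, 6 of 13) and erythrocyte genes 2.64 (adjusted p = 1.4e-05, 9 of 9). Nuclear-encoded respiratory chain genes had a median of -0.31 (adjusted p = 1.1e-08, 0 of 52), branched-chain amino acid breakdown -0.30 (adjusted p = 1.4e-05, 0 of 19) and thermogenesis and brown adipocyte identity -0.30 (adjusted p = 1.4e-05, 0 of 32). All of these had an adjusted p of 0.50 with an estimated correlation, and the respiratory chain call ended without obesity-prone replicate 3 (median -0.05, adjusted p = 0.17). Without that library the medians were -0.13 (adjusted p = 0.014) for branched-chain amino acid breakdown, -0.14 (0.0061) for thermogenesis and 1.09 (0.0018) for erythrocyte genes. Without obesity-prone replicate 2 they were -0.49 for the respiratory chain and -0.51 for thermogenesis. Scd1 averaged 11823 ± 2773 CPM in obesity-prone and 3038 ± 1810 in obesity-resistant libraries (adjusted p = 0.23), and Dio2, the enzyme that activates thyroid hormone in brown fat, 238 ± 177 and 573 ± 231 (adjusted p = 0.28). For Ucp1 the log2 fold change was -0.60 (adjusted p = 0.42). In all, 17 lists were called upward and 8 downward, and the heat shock list was not called (median 0.14, adjusted p = 0.77), but was called lower without obesity-prone replicate 2 (median -0.44, adjusted p = 0.0027).

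Fold changes of lncRNAs followed those of the nearest protein-coding gene. Between obesity-prone and obesity-resistant libraries Spearman's correlation was 0.32 across 2000 pairs within 100 kb, which are genes and not independent replicates. Against control it was 0.35 for obesity-prone and 0.26 for obesity-resistant libraries. The permutation p was 1e-04 in each of the 3, the smallest that 10000 reassignments can give, and the adjusted p was 1e-04. Reassigning partners asks whether neighbouring genes move together, and does not tie this to diet or obesity. In 1003 of the pairs the genes overlap and, with no strand stated, their reads cannot be told apart. Over the 997 pairs that do not overlap, the correlation was 0.26 between obesity-prone and obesity-resistant libraries.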

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

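The tests of heat shock proteins, of obesity-prone replicate 3, of blood cells in control replicate 4 and of other splits were chosen after the results were seen, as was the comparison of control replicate 4 with left-out high-fat diet libraries, and the test of its position over 691 genes was not. Among 147 values tested for 1 control library far from the other 3, 12 stood out, where chance gives about 1 in 20, and 10 of the 12 belonged to control replicate 4. Among those of that library, Slc5a7 was at 0.027 CPM, which is 1 count, against 0 in the others. With 0 in the other 3 libraries any count stands out, so this value carries no weight. Scd3 was at 0.64 CPM (next 0.17), Ubd at 0.35 (next 0.17), Hspb8 at 65.1 (next 37.0), Ifi44 at 1.47 (next 0.56) and Bpgm at 34.7 (next 19.3), and Ppm1k was low at 31.3 (next 58.3). The list scores of control replicate 4 were 0.19 for interferon response (next -0.52) and 0.26 for antioxidant and NRF2 targets (next 0.04). In control replicate 3 Rpl32 was low at 37.7 CPM (next 45.8), and in control replicate 1 the circadian clock score was 0.31 (next -0.02).

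Between obesity-prone and obesity-resistant libraries, both on the high-fat diet, the difference itself was tested, and 25 lists passed at the preset correlation but none with an estimated one (adjusted p from 0.50 to 0.62). Median log2 differences upward were 2.64 for erythrocyte, 1.41 for macrophage, 1.25 for B cell and plasma cell, 0.98 for cell cycle, 0.95 for collagen and extracellular matrix, 0.82 for white adipocyte-selective, 0.79 for neutrophil and mast cell, 0.77 for MHC class II and dendritic cell, 0.70 for T and NK cell, 0.63 for inflammatory cytokines and chemokines, 0.57 for adipocyte progenitor and fibroblast, 0.50 for immediate early, 0.38 for interferon response, 0.29 for cholesterol synthesis, 0.20 for unfolded protein and integrated stress response, 0.15 for endothelial cell and 0.12 for lysosome and autophagy genes. Downward they were -3.05 for skeletal muscle, -0.49 for nerve and Schwann cell, -0.31 for respiratory chain, -0.30 for branched-chain amino acid breakdown, -0.30 for thermogenesis and brown adipocyte identity, -0.28 for glucose uptake and glycolysis, -0.27 for TCA cycle and -0.23 for fatty acid oxidation genes. In obesity-resistant replicates 1 to 3 the glycolysis score (0.01, 0.06 and 0.17) followed the muscle score (-2.41, 1.52 and 3.38). Without obesity-prone replicate 3, 16 lists passed. Calls that ended without it were those of the respiratory chain (-0.05, adjusted p = 0.17), TCA cycle (-0.03, 0.81), fatty acid oxidation (0.024, 0.94), white adipocyte-selective (0.30, 0.16), interferon response (0.14, 0.16), T and NK cell (0.48, 0.21), B cell and plasma cell (1.08, 0.21), endothelial cell (0.09, 0.16), nerve and Schwann cell (-0.44, 0.075) and unfolded protein and integrated stress response lists (0.14, 0.075). Medians that moved by over 1.5 times with the call kept were, without it, -0.14 for thermogenesis, -0.13 for branched-chain amino acid breakdown, -0.09 for glycolysis, 0.51 for neutrophil and mast cell, 1.09 for erythrocyte, 0.34 for progenitor and fibroblast and 0.30 for immediate early genes. Without obesity-prone replicate 2 they were -0.51 for thermogenesis, -0.38 for fatty acid oxidation, -0.48 for glycolysis, -0.49 for respiratory chain, 0.96 for inflammatory cytokine and chemokine and 0.58 for interferon response genes, and without replicate 1 -0.34 for fatty acid oxidation, -0.42 for glycolysis and -0.41 for TCA cycle genes. Without obesity-resistant replicates 3 and 2 they were 1.25 for white adipocyte-selective and 0.32 for unfolded protein and integrated stress response genes. Without obesity-prone replicate 1 the calls of T and NK cell (adjusted p = 0.12), B cell and plasma cell (median 0.80, adjusted p = 0.15) and nerve and Schwann cell genes (0.086) ended, and without obesity-prone replicate 2 those of skeletal muscle (0.063), nerve and Schwann cell (0.052), unfolded protein and integrated stress response (0.052) and lysosome and autophagy genes (0.11). Without obesity-resistant replicate 1 those of T and NK cell (0.060), unfolded protein and integrated stress response (0.14) and lysosome and autophagy genes (0.11) ended, and without replicate 2 those of white adipocyte-selective (0.052), B cell and plasma cell (0.067) and endothelial cell genes (0.22). Without obesity-resistant replicate 3 those of T and NK cell (0.092), B cell and plasma cell (0.092), skeletal muscle (median -1.44, adjusted p = 0.11), endothelial cell (0.063) and nerve and Schwann cell genes (median -0.29, adjusted p = 0.26) ended, and without control replicate 1 that of B cell and plasma cell genes (0.058).

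The heat shock list was called higher in both high-fat diet groups at the preset correlation but not with an estimated one (adjusted p = 0.45 and 0.33), and 0 of 16 members passed in obesity-resistant libraries by edgeR over all genes tested (13 adjusted over the list alone). Skeletal muscle in the samples was argued against as the cause, since with the muscle score as a covariate the list's median log2 fold change was 1.44 in obesity-prone and 1.46 in obesity-resistant libraries. Stress at collection stayed open, since immediate early genes, which such stress also induces, had medians of 0.64 and 0.22 and passed only in the former. The high-fat diet stayed a candidate explanation: the list's score was higher in each of the 6 high-fat diet libraries (lowest 0.08) than in each control (highest -0.50), but the exact permutation p of 0.0048 over 210 splits, the smallest they can give, only restates the pattern that led to the list. Allowing for its choice among 37 lists, the share of splits in which any list had a t statistic as large as that of this list (5.19) was 0.033. Diet cannot be separated from the order or day of collection, which no label gives.

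Obesity-prone replicate 3 stood apart from the other 2 obesity-prone libraries. Erythrocyte and macrophage genes were higher in it (median log2 ratios 2.74 and 1.08), but dilution of adipocyte RNA by other cells was argued against as the whole cause of the lower respiratory chain genes, since the log2 ratio of general adipocyte genes lay above that of respiratory chain genes by 0.86 (medians -0.15 and -1.01). White-type adipocytes in place of brown-type ones may account for the difference. The median log2 ratio was 2.65 over 15 white adipocyte-selective genes other than Hox genes, 13 of them above 0, and -0.98 over thermogenesis genes. Members of both lists also went the other way. Hoxc8, of the white list, was at 0.79 CPM in replicate 3 against 5.57 and 1.99 in replicates 1 and 2. Tbx15, of the thermogenesis and brown adipocyte identity list, was at 12.6 CPM against 2.42 and 2.86. Both were picked after their values were seen. Posterior white fat taken with the sample stayed open, with a median of -0.90 over 8 posterior Hox genes of which 4 were below 0. Whether the white-type genes reflect dissection or a change of the tissue in this mouse was not tested.

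Control replicate 4 lay between the other controls and the high-fat diet libraries. Over the 691 genes called in both comparisons without it, its median position from the other controls (0) to the high-fat diet mean (1) was 0.65 (quartiles 0.48 and 0.85), and on the same scale the scores of the whole heat shock and lipogenesis lists put it at 0.27 and 0.89. For a high-fat diet library under a control name this was undecided, lying between the bounds set beforehand (at least 0.75 for, below 0.5 against). The argument against it rests on the test added afterwards, with genes chosen without replicate 4 and without 1 high-fat diet library at a time. There the mean position of control replicate 4 was 0.63, while the left-out high-fat diet libraries lay at 0.87 to 1.07 (SD 0.080). No other control was left out in the same way, so the test does not show where a true control would lie. Blood and lymphoid cells in the sample stayed open too, since lipogenesis genes lay at -0.62 relative to general adipocyte genes (medians -0.79 and -0.17), within the spread of the former (0.67). No biological explanation was tested.

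Other splits of the same libraries did not exclude chance for the counts against control. For obesity-prone libraries 2 of 35 splits gave as many genes (1377, highest other 2213), 2 as many lncRNAs (118, highest other 166) and 9 as many lists (23, highest other 28). For obesity-resistant libraries 2 of 35 splits gave as many genes (28, highest other 801), 2 as many lncRNAs (1, highest other 67) and 21 as many lists (14, highest other 24). The splits with more genes set control replicates 1 to 3 against control replicate 4 with the high-fat diet libraries, and a call of 801 against 28 points to a structure of the samples. Among the 8 splits that part the 3 same-numbered pairs of control and obesity-resistant libraries, 2 gave as many genes (highest other 801) and 3 as many lists (highest other 16). These 8 splits are too few for a share under 0.05. Between obesity-prone and obesity-resistant libraries 10 splits are too few for a share under 0.05: 10 gave as many genes (0 by edgeR, highest other 1; 3030 at an unadjusted p below 0.05, 565 by DESeq2), 10 as many lncRNAs (0, highest other 0; 292 unadjusted, 45 by DESeq2) and 2 as many lists (25, highest other 25).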

How the results depend on the processing

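Tests without obesity-prone replicate 3 and control replicate 4, without genes that have no name, with the skeletal muscle score and without overlapping pairs were chosen after seeing the data. For obesity-prone against control libraries, the 1377 genes and 118 lncRNAs became 3138 and 210 in DESeq2, 49 and 3 with only the 2 groups fitted, 2660 and 185 without obesity-prone replicate 3 and control replicate 4, and 543 and 44 with the skeletal muscle score, and 544 genes were also at least 2-fold. The 23 lists became 0 with an estimated correlation and 2 in fry. Leaving out 1 library gave 76 to 3034 genes, 6 to 225 lncRNAs and 18 to 27 lists. For obesity-resistant against control libraries, the 28 genes and 1 lncRNA became 1138 and 98 in DESeq2, 76 and 5 with no filter, 68 and 4 with the stricter one, 361 and 29 with only the 2 groups fitted, 383 and 33 with the replicate block, which leaves out control replicate 4 (856 and 76 in the same libraries without the block), 2214 and 149 without obesity-prone replicate 3 and control replicate 4, 75 and 6 without genes that have no name, and 53 and 6 with the skeletal muscle score. Limma on FPKM gave 4, 2 and 5 lncRNAs with 0.5, 0.1 and 1 added, and 51 genes with 1 added. The 14 lists became 0 with an estimated correlation and 1 in fry. Leaving out 1 library gave 3 to 856 genes, 0 to 76 lncRNAs (345 unadjusted with all libraries in edgeR, 98 in DESeq2) and 12 to 16 lists. For obesity-prone against obesity-resistant libraries, 0 genes (edgeR, 3030 unadjusted) became 565 in DESeq2, with 45 lncRNAs, and the 25 lists became 0 with an estimated correlation and 0 in fry. Leaving out 1 library gave 0 to 885 genes, 0 to 63 lncRNAs and 16 to 25 lists. The 25 shared calls became 64 with the stricter filter, 1460 without obesity-prone replicate 3 and control replicate 4, 68 without genes that have no name and 40 with the skeletal muscle score, 1, 3, 6, 7 and 1 in 5 of the 6 ways to share out the controls 2 and 2, and 3 to 691 on leaving out 1 library. For obesity-prone against control libraries the replicate block gave 1574 genes and 124 lncRNAs, against 3034 and 225 in the same libraries without it. RLE and upper-quartile factors gave 1327 and 1419 genes for obesity-prone and 26 and 38 for obesity-resistant against control libraries, each within 1.5 times the reported count. Of the lists between obesity-prone and obesity-resistant libraries, fatty acid oxidation ranged from -0.38 to 0.024 on leaving out 1 library and reversed without obesity-prone replicate 3 (0.024, adjusted p = 0.94, range 1.4e-06 to 0.94). Heat shock proteins ranged from -0.44 to 0.33 and reversed without obesity-prone replicate 2 (-0.44, adjusted p = 0.0027, range up to 0.96). No named gene that had passed changed direction under any alternative run. The cause of these changes was not tested. Depth, at 35583997 to 37327770 counts, limits genes at a few counts, such as Slc5a7 with 1 count in control.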

Other observations

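The genes and libraries named here were picked after their values were seen, while the test of receptor targets was chosen before the values of the targets were seen. Cyp1a1 was lower in both high-fat diet groups, and lower activity of the aryl hydrocarbon receptor, which induces it, was put as a hypothesis that could explain the fall. Of 8 other target genes 5 were tested (Cyp1b1, Tiparp, Nqo1, Ugt1a6a and Ugt1a6b), with a median log2 fold change of 0.41 in obesity-prone and -0.48 in obesity-resistant libraries. None of the 5 passed in either comparison with control (adjusted p from 0.24 to 0.76), and the targets leave the hypothesis open.

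Skeletal muscle transcripts differed between libraries of each group, with Acta1 from 0.17 to 129.8 CPM and Myh4 from 0.027 to 263.7 CPM. Hba-a1, whose reads cannot be told with certainty from those of its near-identical copy, was at 8421 CPM in obesity-prone replicate 3 and 2274 CPM in control replicate 4. Mest was at 160.5 CPM in obesity-prone replicate 3 and at most 29.4 CPM in the other libraries. A single gene without a name took 16.1% to 21.2% of the counts of a library. Ucp3 had a log2 fold change of -1.48 (adjusted p = 0.011) in obesity-prone against control libraries, and the neighbouring lncRNA Gm10603 -0.89 (adjusted p = 0.0092).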
